A study of Mus musculus with 8 samples.

How the data were processed

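Single-cell RNA profiles were measured in mouse bone marrow cells sorted as negative for lineage markers and positive for Kit and Sca1, the compartment that holds hematopoietic stem cells and multipotent progenitors. The 8 samples fall into 4 groups of 2: controls that carry only the Vav-Cre driver of blood-cell recombination (WT), and mice heterozygous for Idh1 R132H, Idh2 R140Q or Idh2 R172K with the same driver. Per the labels, the strain is C57Bl/6J and each sample is a pool of mice that counts as a biological replicate. The labels speak of 4 pools of 2 mice for each genotype, and 2 samples per genotype are used here. The p-values therefore measure the spread between pools. Counts per gene do not tell the mutant from the unmutated allele, so the Idh1 and Idh2 levels do not check the labels.

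The authors' deposited matrices hold whole-number counts per gene and cell barcode for 27998 genes, with no normalization, taken here as counts of unique molecular identifiers (UMIs). Per the submitters' processing notes, Cell Ranger and Seurat 2.1.0 were used and the builds GRCm38 and mm10 are named. The version of Cell Ranger, the library kit, the strand setting and the filter that chose the deposited barcodes are not given in the sources used here. A filter applied before deposit would raise the lowest depth seen, which was 2653 UMIs per barcode in Idh2 R172K sample 2. Gene symbols and identifiers come from the files, and coordinates from the GENCODE M21 annotation of GRCm38, in which 12739 of the 12777 tested identifiers were found. Genes with near-identical copies, such as Hspa1a, Xlr4b, Rpl39l and the ribosomal protein genes, are uncertain because the authors' counting could split or drop their reads. Tnfsf13os is an antisense gene and is uncertain too.

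Cells with at least 1000 detected genes and under 10% of UMIs from mitochondrially encoded genes were kept, which left 99.3 to 99.9% of the barcodes. No upper limit was set. Scrublet (run from scanpy 1.11.5) marked 16 of the 14352 kept cells (0.11%), so it did not work as a doublet caller and its removal is only an alternative. Xist and transcripts of 4 Y-linked genes gave a second readout: 300 cells, 2.6% of the cells called female, male or both, held transcripts of both sexes. Cells were called female with at least 4 Xist UMIs and fewer than 2 Y-linked UMIs, as holding both sexes' transcripts with at least 4 and at least 2, and male with at least 1 Y-linked UMI and at most 1 Xist UMI. These sex thresholds were set after seeing the data.

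UMI counts were summed over the kept cells of each sample, and the sums are the values tested, because cells are not replicates. They came to 14533190 to 32771825 UMIs per sample. All 8 samples entered 1 edgeR 4.0.16 fit (R 4.3.3, filterByExpr, TMM factors, robust quasi-likelihood, 4 residual degrees of freedom), and genes were called at an adjusted p of 0.05 after Benjamini-Hochberg adjustment within a comparison. The biological coefficient of variation was 10.9%. Fold changes are log2 values with standard errors, and levels are CPM (UMI counts scaled to a fixed library total) with the SD over 2 samples. A gene without counts in a group has a lower bound on its fold, computed with 3 counts over the group. Before averaging, the replicates of each group were compared by chi-square over genes, which gave 17.5 to 22.7 per gene, so no pair of samples agreed within sampling noise.

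The named genes follow a rule fixed before the data were examined. For a mutant against WT they are Idh1 and Idh2, the 8 highest and 8 lowest fold changes among called genes with a mean of at least 10 CPM and no overlap between the samples of the groups, and up to 3 called members of each fixed list with the smallest adjusted p. Between mutants the rule takes 4 and 4, and within a cell class 3 and 3. Sex-linked genes and unnamed gene models take no place. The 26 gene lists and the cell type markers were fixed at the same time. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over the lists. An estimated correlation and fry were the alternatives.

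Cells were clustered in Python 3.11.15 with numpy 2.4.6, scikit-learn 1.9.0 and leidenalg 0.10.2 on log values scaled to 10000 UMIs per cell, with 30 principal components, 20 neighbours and 2000 variable genes, without mitochondrial, ribosomal, sex-linked and cycle genes, at Leiden resolution 1. Clusters were named from the fixed markers. A name needed at least 3 raised markers, at least 1 marker among the 10 leading genes, a positive mean score and, with under 3 markers among those 10, the highest score of all classes. These conditions were set after seeing the data, and a looser rule that needs only the 3 raised markers was added beside them. Class shares were tested with edgeR on cell numbers and with an exact permutation test over the 4 groups, whose smallest p is 1 in 105. Genes were tested within each class that had at least 30 cells in every sample. For shares of cells with a marker, cells were thinned to 3000 UMIs. Fold changes of 2 mutants share the WT samples, so unchanged groups were simulated against the same WT samples in 40 draws. The 2 WT pools are too few to be split so that each mutant has 2 of its own.

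The gene test was tested on simulated counts with 200 changed genes. For Idh1 R132H against WT it recovered 26.9% of 1.5-fold, 68.7% of 2-fold and 86.4% of 4-fold changes, with 15 false calls among 12538 genes. For Idh2 R140Q against WT the shares were 26.9%, 79.1% and 90.9% with 18 false calls among 12531 genes. For Idh2 R172K against WT they were 52.2%, 56.7% and 90.9% with 9 false calls among 12540 genes. The false calls lie above the nominal 5% of calls in these runs.

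Alternatives fixed before the data were examined were no low-count filter, DESeq2 size factors, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, the replicate number as a block, other cell filters, thinning to the smallest total, equal class weights, other clusterings, and leaving out each sample. Added after seeing the data were the split by sex, removal of cells with transcripts of both sexes, cells with at least 6000 UMIs, HSC-like cells of a clustering centred within samples, and the looser naming rule. With 1 sample of a group left out, the lone sample is assumed to vary like the other groups. Groups of 2 are too small for an outlier test or for a count of other splits of the samples. Figures were drawn with matplotlib 3.10.9.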

Results

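Gene expression was measured cell by cell in bone marrow stem and progenitor cells of 3-4 month old mice. The sorted compartment lacks lineage markers and carries Kit and Sca1. Cells of control mice (WT) were set beside cells of mice with the Idh1 R132H, Idh2 R140Q or Idh2 R172K mutation, with 2 pools of mice in each of the 4 groups. Idh1 and Idh2 are the cytosolic and the mitochondrial NADP-dependent isocitrate dehydrogenases. The mutant enzymes make 2-hydroxyglutarate, which inhibits dioxygenases that use 2-oxoglutarate. After filtering, the WT pools held 1647 and 1517 cells, the Idh1 R132H pools 1338 and 1979, the Idh2 R140Q pools 886 and 2172, and the Idh2 R172K pools 2089 and 2724. In the same order the totals were 19283142, 22009364, 19977839, 32771825, 14533190, 25540634, 19949440 and 25821826 UMIs. The median depth per cell was 9783 and 12189 UMIs in WT and 8322 and 8403 in Idh2 R172K, the lowest of the 8 pools. All pools mixed the sexes, with 37.2 to 66.1% female cells among cells called female or male. Intervals and lower bounds below cover counting error only.

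The comparison of Idh1 R132H with WT asks what this mutation does to gene expression in the compartment. No single gene passed the test. Idh1 itself stood at 15.4 ± 1.6 CPM (SD, n = 2) in WT and 19.4 ± 1.5 in Idh1 R132H, a log2 fold change of 0.34 ± 0.16 (SE) with an adjusted p of 0.89. Idh2 stood at 242 ± 3.4 and 259 ± 23 CPM (log2 0.10, adjusted p 0.92). The edgeR count of 0 genes stands beside 712 genes at an unadjusted p under 0.05 and 0 genes by DESeq2. It was 1 without Idh2 R140Q sample 1 or sample 2, and 195 without the low-count filter. Only 2 of those 195 genes lie outside the tested set, so they are not low-count genes, and the cause was not tested. A fit of these 2 groups alone called 10 genes, 4 higher and 6 lower.

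Between these groups 10 of the 26 lists moved as groups by camera, while 0 of their members passed on their own. Each of these 10 calls was lost with an estimated correlation, at an adjusted p of 0.788, and fry called none. HSC genes lay lower (mean log2 −0.23, adjusted p 0.0021, 0.788 with an estimated correlation). Genes of granules and the myeloid lineage lay higher (mean 0.15, adjusted p 0.0065), as did S phase genes (mean 0.082, 0.0065), G2 and M phase genes (mean 0.069, 0.0075) and cholesterol synthesis (mean 0.20, adjusted p 0.00092), all at an adjusted p of 0.788 with an estimated correlation. Granulocyte-monocyte-primed-like cells made up 16.3 and 26.1% of the Idh1 R132H pools and 13.7 and 12.9% of the WT pools. Heme synthesis (0.024), MHC class II (0.019), glycolysis (0.023), the TCA cycle (0.022) and 2-hydroxyglutarate and 2-oxoglutarate metabolism (0.019) lay higher too, again at an adjusted p of 0.788 with an estimated correlation. Within lymphoid-primed-like cells the means were −0.011 for the TCA cycle and −0.0080 for 2-hydroxyglutarate and 2-oxoglutarate metabolism, and the test of G2 and M phase genes turned (mean 0.0037). The S phase mean was −0.012 within granulocyte-monocyte-primed-like cells, and the MHC class II mean −0.14 in HSC-like cells of the centred clustering. Cholesterol synthesis alone stayed called with each pool left out in turn. Without Idh1 R132H sample 2 the adjusted p was 0.263 for HSC genes, heme synthesis, G2 and M phase genes and glycolysis, 0.619 for granule and myeloid genes, 0.785 for S phase genes and the TCA cycle, and 0.431 for 2-hydroxyglutarate and 2-oxoglutarate metabolism. Without WT sample 2 it was 0.159 for granule and myeloid genes, 0.856 for heme synthesis, 0.512 for S phase genes, 0.998 for G2 and M phase genes, 0.203 for MHC class II, 0.14 for glycolysis, 0.153 for the TCA cycle and 0.0847 for 2-hydroxyglutarate metabolism. It was 0.208 for MHC class II without Idh1 R132H sample 1, 0.0693 for glycolysis and 2-hydroxyglutarate metabolism without WT sample 1, and 0.0519 for glycolysis without Idh2 R172K sample 2. Adjusted over the list alone, 1 heat shock gene, Hspa1a, and 1 transcription factor gene lay lower. The other lists were not called: lymphoid priming (adjusted p 0.99), megakaryocyte (0.11), erythroid (0.96), interferon (0.54), heat shock (0.13), hypoxia (0.91), oxidative phosphorylation (0.11), mitochondrially encoded (0.11), dioxygenases (0.85), imprinted (0.54), p53 (0.36), integrated stress (0.26), transcription factors (0.18), NF-kB (0.54), ribosomal (0.72) and sex-linked (0.56). The calls below were made with 1 pool left out, and with an estimated correlation the lowest adjusted p in any fit was 0.40. The erythroid genes turned with the WT pool used: without WT sample 1 they lay higher (mean 0.96, adjusted p 3.6e-07), and without WT sample 2 lower (mean −0.96, adjusted p 4.3e-07). Without Idh1 R132H sample 2 the immediate early and heat shock genes lay higher (adjusted p 2.3e-05) and mitochondrially encoded genes lower (0.046). Without Idh1 R132H sample 1 oxidative phosphorylation (0.00028) and the integrated stress response (0.017) lay higher and hematopoietic transcription factors lower (0.014). Megakaryocyte genes lay higher without WT sample 1 (0.040), Idh2 R172K sample 1 (0.0077) or Idh2 R172K sample 2 (0.013), and ribosomal proteins lower without WT sample 1 (0.0063). The mean, the median and the test differ in sign for the interferon, hypoxia, dioxygenase, stress response and ribosomal lists.

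In Idh2 R140Q against WT, 3 genes passed the test. Hddc3, whose product hydrolyses the alarmone ppGpp, rose from 7.20 ± 0.29 CPM to 23.1 ± 7.2 (log2 1.70 ± 0.18, adjusted p 0.0033). It lies on chromosome 7 from 80343104 to 80350547 (GRCm38), near Idh2 at 80094846 to 80115392. Lag3, an inhibitory receptor that binds MHC class II on chromosome 6 from 124904361 to 124911705, rose from 10.2 to 19.5 ± 3.2 CPM (log2 0.95 ± 0.13, adjusted p 0.024). Xlr4b of the X-linked lymphocyte-regulated family fell by 1.37 on the log2 scale (adjusted p 0.024). It lies outside the rule for named genes and was chosen after its values were seen. Idh1 (log2 0.054, adjusted p 0.99) and Idh2 (−0.045, adjusted p 0.99) did not pass.

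These 3 calls stand beside 594 genes at an unadjusted p under 0.05 and 4 genes by DESeq2. The count was 0 without WT sample 1, 1 without WT sample 2, 12 and 13 without Idh2 R140Q sample 1 and sample 2, and 10 without either Idh2 R172K sample. Hddc3 had an adjusted p of 0.322 without WT sample 1, 0.0747 without WT sample 2 and 0.0597 in a fit of these 2 groups alone, where 6 genes passed. Lag3 had 0.437 without WT sample 1, 0.163 without WT sample 2, 0.0919 without Idh2 R140Q sample 2 (log2 0.81) and 0.061 with the replicate number as a block. The call of Xlr4b was lost without WT sample 1 (adjusted p 0.322), WT sample 2 (0.163), Idh1 R132H sample 2 (0.0599), Idh2 R140Q sample 1 (0.0549) or sample 2 (0.0583), and after thinning to the smallest total (0.0537). In female cells alone none of the 3 passed (log2 1.36 and adjusted p 0.983 for Hddc3, 0.78 and 0.983 for Lag3, −1.46 and 0.127 for Xlr4b). In male cells Hddc3 (2.16, 4.1e-05) and Lag3 (1.23, 0.0018) passed and Xlr4b did not (−1.41, 0.159). The sex split was chosen after the data were seen. Without the low-count filter 258 genes passed, of which 4 lie outside the tested set.

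**Figure D1:**
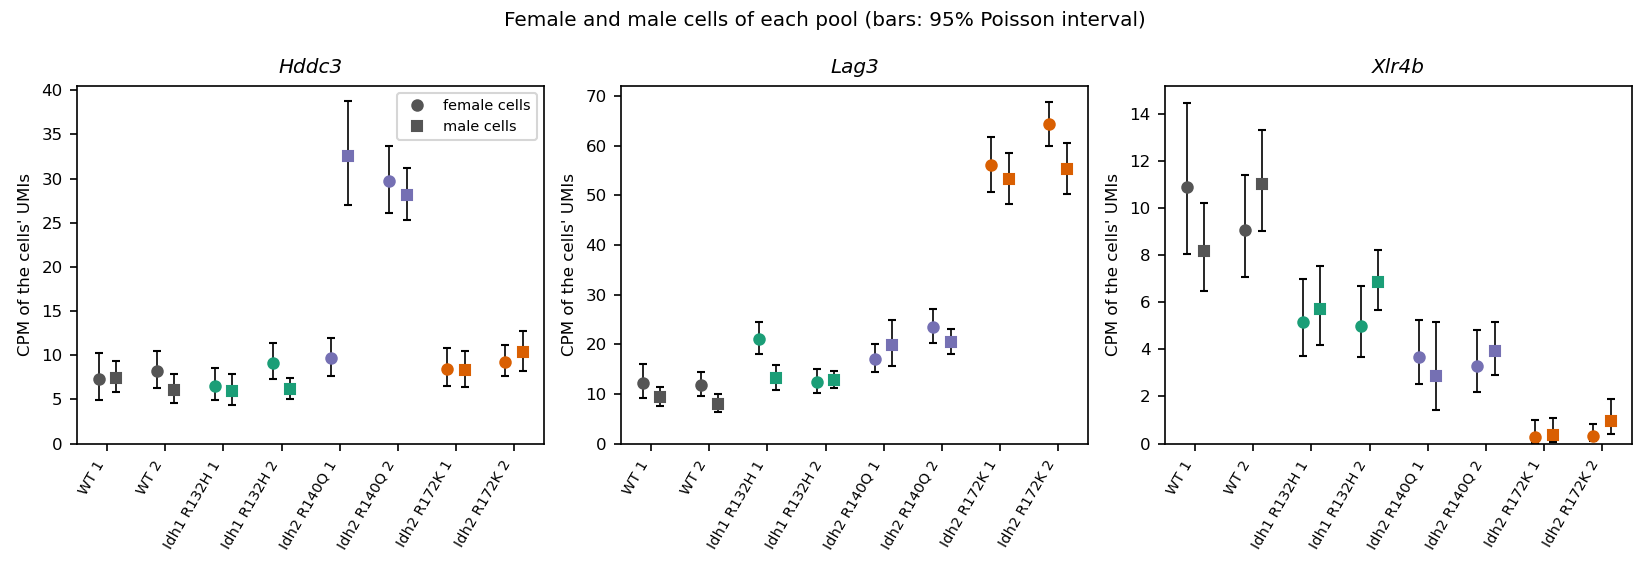
Levels of Hddc3, Lag3 and Xlr4b (vertical axes, CPM of the cells' UMIs) in female cells (circles) and male cells (squares) of each of the 8 pools, with 95% Poisson intervals. Hddc3 was 9.65 CPM in the female cells of Idh2 R140Q sample 1 and 32.5 in its male cells.

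Among the fixed lists, 10 moved in Idh2 R140Q against WT by camera, again with 0 members called. All 10 calls were lost with an estimated correlation, at an adjusted p of 0.775, and fry called none. Higher were HSC genes (mean log2 0.11, adjusted p 0.027), megakaryocyte genes (0.18, adjusted p 0.0076), MHC class II (0.46, adjusted p 0.00035), cholesterol synthesis (0.26, adjusted p 3.7e-05), dioxygenases (0.085, adjusted p 0.015) and ribosomal proteins (0.071, adjusted p 0.00021), each at 0.775 with an estimated correlation. Lower were G2 and M phase genes (−0.18, adjusted p 8.6e-11), interferon genes (−0.16, adjusted p 0.0079), the TCA cycle (−0.10, adjusted p 0.0042) and oxidative phosphorylation (−0.084, adjusted p 0.0013), at an adjusted p of 0.775 with an estimated correlation. Granulocyte-monocyte-primed-like cells made up 13.9 and 5.06% of the Idh2 R140Q pools. In female cells alone, a split chosen after the data were seen, the means turned to 0.17 for interferon genes, 0.051 for the TCA cycle and 0.074 for oxidative phosphorylation, which was then called higher (adjusted p 0.043, 0.921 with an estimated correlation). The HSC mean turned to −0.10 in lymphoid-primed-like cells. In HSC-like cells of the centred clustering it was −0.068, with −0.050 for megakaryocyte genes, 0.082 for the TCA cycle and 0.014 for oxidative phosphorylation, and the test of MHC class II turned too. G2 and M phase genes alone stayed called with each pool left out. Without Idh2 R140Q sample 2 the adjusted p was 0.453 for HSC genes, 0.749 for interferon genes, 0.927 for oxidative phosphorylation, 0.17 for cholesterol synthesis, 0.11 for megakaryocyte genes and MHC class II, 0.28 for the TCA cycle and 0.0635 for dioxygenases. Without Idh2 R140Q sample 1 it was 0.0946 for ribosomal proteins, 0.134 for dioxygenases and 0.0537 for megakaryocyte genes, and without WT sample 1 0.472 for ribosomal proteins and 0.0857 for dioxygenases. Without WT sample 2 it was 0.166 for megakaryocyte genes, 0.16 for HSC genes and 0.064 for interferon genes. Adjusted over the list alone, 2 HSC genes and 1 cholesterol gene lay higher and 1 heat shock gene lower. The lists not called were lymphoid priming (adjusted p 0.063), granule and myeloid (0.17), erythroid (0.14), heme (0.63), S phase (0.10), heat shock (0.12), hypoxia (0.84), glycolysis (0.49), mitochondrially encoded (0.30), 2-hydroxyglutarate (0.74), imprinted (0.14), p53 (0.27), integrated stress (0.084), transcription factors (0.17), NF-kB (0.056) and sex-linked (0.74). The next calls were made with 1 pool left out, and with an estimated correlation the lowest adjusted p in any fit was 0.381. Here too the erythroid genes lay higher without WT sample 1 (mean 1.45, adjusted p 2.2e-12) and lower without WT sample 2 (mean −0.46, adjusted p 0.00089). Without Idh2 R140Q sample 1 the lymphoid priming genes (adjusted p 7.0e-05) and NF-kB targets (0.00029) lay higher and the granule and myeloid genes lower (3.1e-05). Lymphoid priming genes also lay higher without WT sample 2 (0.021) or Idh1 R132H sample 1 (0.039) or sample 2 (0.048), and S phase genes lower without WT sample 2 (0.0035). NF-kB targets also lay higher without Idh1 R132H sample 1 (0.017) or sample 2 (0.022) or Idh2 R172K sample 1 (0.028) or sample 2 (0.047). Signs of mean, median and test differ for the hypoxia, 2-hydroxyglutarate and sex-linked lists.

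Idh2 R172K cells stood far from WT, with 3365 of 12777 genes changed, 1527 higher and 1838 lower. Median genes per cell were 2509 and 2504 in its pools and 2818 to 3451 in the 6 others. Mitochondrially encoded genes took a median of 3.41 and 3.60% of a cell's UMIs, beside 2.56 to 2.80%, and the 10 top genes took 9.13 and 9.29% of all UMIs, beside 7.53 to 8.49%. Smagp, a small cell adhesion glycoprotein (chromosome 15, 100621339 to 100636940), rose from 3.05 ± 0.64 to 34.2 ± 8.6 CPM (log2 3.44 ± 0.24, adjusted p 1.5e-05). Perp, a membrane protein and p53 target (chromosome 10, 18845020 to 18857073), rose from 2.24 ± 0.17 to 20.2 ± 1.0 CPM (3.12 ± 0.20, adjusted p 4.4e-07). Selp, which encodes P-selectin of platelets and endothelium (chromosome 1, 164115264 to 164150026), rose from 5.88 ± 1.7 to 45.0 ± 5.1 CPM (2.89 ± 0.36, adjusted p 0.0042). Lag3 rose to 57.8 ± 4.4 CPM (2.46 ± 0.13, adjusted p 1.3e-07). The secreted Igfbp7 (log2 2.47), the protocadherin Pcdh7 (2.28) and Plxdc2 (2.24) rose as well. Tmem215 (2.45 ± 0.62, adjusted p 0.049) lost its call without either sample of WT, Idh1 R132H or Idh2 R172K, with adjusted p values up to 0.193. Idh2 rose from 242 to 374 ± 5.9 CPM (0.59 ± 0.10, adjusted p 0.0013), and Idh1 did not pass (−0.11, adjusted p 0.64).

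Among the lowest genes, 2 were without counts in Idh2 R172K. Slc16a11 of the monocarboxylate transporter family (chromosome 11, 70212752 to 70216417) stood at 23.0 ± 2.0 CPM in WT and was at least 350-fold lower (adjusted p 0.0019), a bound of 197-fold and 152-fold without Idh2 R172K sample 1 and sample 2. Car1, the carbonic anhydrase of red cells (chromosome 3, 14766216 to 14808368), stood at 100 ± 95 CPM in WT and was at least 1461-fold lower (adjusted p 0.042). This bound was 508-fold without WT sample 1, 2549-fold without WT sample 2, and 824-fold and 637-fold without Idh2 R172K sample 1 and sample 2. Padi4, which citrullinates histones (chromosome 4, 140745865 to 140774236), fell from 29.3 ± 5.0 to 1.52 ± 0.59 CPM (−4.27 ± 0.26, adjusted p 1.9e-05). Ccnd1, which encodes cyclin D1 (chromosome 7, 144929931 to 144939925), fell from 20.2 to 1.60 CPM (−3.69 ± 0.20, adjusted p 1.3e-07). Bex4 (log2 −3.28), the inflammatory caspase Casp1 (−2.88) and the thromboxane receptor Tbxa2r (−2.60) fell too. Ctsg, the granule protease cathepsin G, fell from 367 ± 41 to 67.1 ± 10 CPM (−2.49 ± 0.56, adjusted p 0.040). The calls of Car1 and Ctsg were lost in 6 of the fits that left out 1 pool, with adjusted p values up to 0.118 for Car1 and 0.193 for Ctsg.

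**Figure D2:**
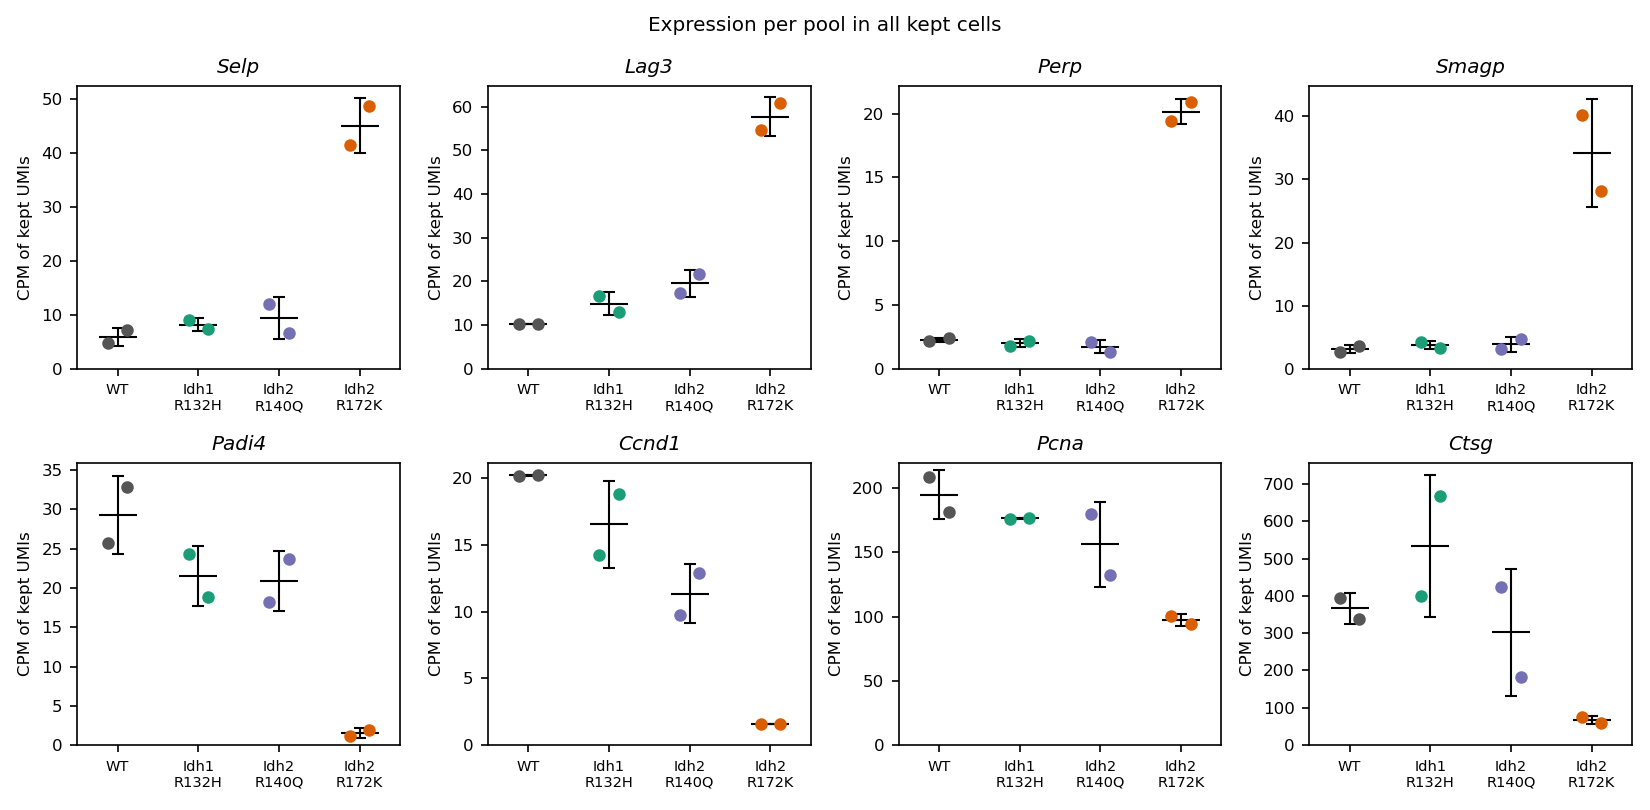
Expression of 8 genes (vertical axes, CPM of kept UMIs) in each pool of the 4 groups, with points for pools, long bars for means and whiskers for the SD of 2 pools. The Idh2 R172K pools lie above all others for Selp, Lag3, Perp and Smagp and below all others for Padi4, Ccnd1, Pcna and Ctsg.

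Genes of the blood lineages moved in different directions in Idh2 R172K. Of 24 erythroid genes 2 rose and 10 fell (camera adjusted p 3.1e-05, 0.832 with an estimated correlation), among them Ctse (log2 −1.74), Rhag (−3.44) and the transferrin receptor Tfrc (−0.57). Of 17 heme synthesis genes 1 rose and 9 fell (adjusted p 0.031, 0.832 with an estimated correlation), with Alad from 61.5 to 29.8 CPM (−1.08) and Abcb6 (−1.51), while Hmox1, which degrades heme, rose (1.76). Of 21 megakaryocyte genes 7 rose and 0 fell (adjusted p 0.0498, 0.832 with an estimated correlation), with Rab27b (log2 1.47) and Plek (1.16) among them. Gp1bb (−1.81) and Pf4 (−0.14) did not pass. A single cell held 741 of the 980 Pf4 UMIs of Idh2 R172K sample 2. Without the top cell of each pool Pf4 went from 38.0 to 9.26 CPM in that pool, beside 5.92 in Idh2 R172K sample 1 and 28.0 and 14.5 in WT, which was not tested. Of these 3 lists fry called heme synthesis (adjusted p 0.034). The erythroid call held with each pool left out, the megakaryocyte call did not without WT sample 2 (adjusted p 0.0556), Idh2 R140Q sample 1 (0.0589) or Idh2 R172K sample 2 (0.788), and the heme call did not without WT sample 1 (0.0767). Rhag lost its call without WT sample 1 (adjusted p 0.0959), Idh2 R172K sample 1 (0.103) or sample 2 (0.0767), and Tfrc without either sample of WT or Idh2 R172K (up to 0.117).

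Of 25 HSC genes 7 rose and 3 fell (camera adjusted p 0.30), with the proto-oncogene Mycn from 24.6 to 52.9 CPM (log2 1.07) and the regulator Prdm16 (−2.71). Of 23 lymphoid priming genes 2 rose and 3 fell (adjusted p 0.51), with Lsp1 (log2 −0.63) and the recombinase gene Rag1 (1.92), whose adjusted p was 0.0502 without WT sample 2. Of 25 granule and myeloid genes 1 rose and 3 fell (adjusted p 0.11), and the list was called as lower without WT sample 2 (0.046) or Idh2 R140Q sample 1 (0.037) or sample 2 (0.038), and in no fit with an estimated correlation (lowest adjusted p 0.447). Within granulocyte-monocyte-primed-like cells it lay higher (mean 0.51, 0.00010) and the HSC list lower (−0.65, 0.021), both at an adjusted p of 0.606 with an estimated correlation. The granule and myeloid genes called in all kept cells were Csf3r, the G-CSF receptor (0.62), Clec12a (−0.99), Ctsg and Irf8. Irf8, a regulator of monocyte and dendritic cell fate, went from 98.5 to 55.1 CPM (−0.88). Of 46 transcription factor genes 12 rose, with Ikzf2 (0.63) among them, and 5 fell (adjusted p 0.19, mean −0.035, median 0.092). Adjusted over the list alone, 9 HSC genes rose and 3 fell, 2 lymphoid genes rose and 3 fell, 1 myeloid gene rose and 2 fell, 8 megakaryocyte genes rose and 1 fell, 2 erythroid genes rose and 14 fell, 1 heme gene rose and 10 fell, and 12 transcription factor genes rose and 6 fell.

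Cell cycle and energy metabolism lists fell in Idh2 R172K, whose cells had a median mitochondrial share of 3.41 and 3.60% (2.56 to 2.80% elsewhere). All 5 calls below had an adjusted p of 0.832 with an estimated correlation, and fry called glycolysis (adjusted p 0.026) among them. Of 42 S phase genes 1 rose and 22 fell (adjusted p 2.6e-05, 0.832 with an estimated correlation), with Pcna, the clamp of DNA polymerase, from 195 to 97.4 CPM (log2 −1.04), and Tyms (−0.67). Of 54 G2 and M phase genes 0 rose and 14 fell (adjusted p 0.031, 0.832 with an estimated correlation), with Anp32e (−0.80), Tubb4b (−0.67) and Cks2 (−0.51). Of 54 nuclear genes of oxidative phosphorylation 0 rose and 24 fell (adjusted p 2.1e-06, 0.832 with an estimated correlation), with Ndufa4 (−0.58), Ndufb6 (−0.68) and Ndufa9 (−0.58) of complex I or IV. TCA cycle genes fell in 11 of 24 cases and rose in 1, Idh2 (adjusted p 0.0038, 0.832 with an estimated correlation), with Idh3a (−0.65) and Ogdh (−0.57). Glycolysis genes fell in 7 of 17 cases and rose in 1 (adjusted p 0.022, 0.832 with an estimated correlation), with Ldhb from 48.0 to 18.6 CPM (−1.40) and Hk3 (−2.32). Within granulocyte-monocyte-primed-like cells G2 and M phase genes lay higher (mean 0.25, adjusted p 0.0023, 0.67 with an estimated correlation), and in HSC-like cells of the centred clustering the TCA mean was 0.049. The G2 and M call was lost without WT sample 1 (adjusted p 0.539) or Idh2 R172K sample 1 (0.285), and Cks2 had 0.0571 without Idh2 R172K sample 2. Of the 13 mitochondrially encoded genes 3 rose and 1 fell (adjusted p 0.76, mean −0.048, median −0.0085, test up), with mt-Co1 from 4691 to 9292 CPM (0.95) and mt-Co2 (0.51). Adjusted over the list alone, 2 S phase genes rose and 26 fell, 14 G2 and M genes fell, 32 oxidative phosphorylation genes fell, 1 TCA gene rose and 12 fell, 1 glycolysis gene rose and 7 fell, and 3 mitochondrially encoded genes rose and 2 fell.

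The list of DNA methylation genes and 2-oxoglutarate dioxygenases rose in Idh2 R172K, with 15 of 28 genes higher and 2 lower (adjusted p 0.0014, 0.832 with an estimated correlation), among them the histone demethylases Kdm5b (log2 0.72), Kdm6b (0.71) and Kdm3a (0.80). Tet1 (0.45), Tet2 (0.48), Tet3 (0.30) and Dnmt3a (0.33) passed too and were chosen after their values were seen. The p53 targets rose, with 7 of 21 higher and 1 lower (adjusted p 0.022, 0.832 with an estimated correlation), with Perp, the proapoptotic Pmaip1 (1.56) and, lower, the death receptor Tnfrsf10b (−1.83). Fry called the dioxygenases (adjusted p 0.026). The p53 call was lost without WT sample 1 (adjusted p 0.0767) or Idh2 R172K sample 1 (0.0684). Tnfrsf10b was lost without WT sample 1 (0.064) and Pmaip1 without WT sample 2 (0.0565) or Idh2 R172K sample 1 (0.0563). Of 20 genes of 2-hydroxyglutarate and 2-oxoglutarate metabolism 2 rose and 7 fell (adjusted p 0.19), and of 12 imprinted genes 3 rose and 1 fell (adjusted p 0.51), with the Notch ligand relative Dlk1 (2.20) and Sgce (0.93). Adjusted over the list alone, 16 dioxygenase genes rose and 3 fell, 8 p53 targets rose and 1 fell, 2 genes of 2-hydroxyglutarate metabolism rose and 7 fell, and 4 imprinted genes rose and 1 fell.

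Stress and immune lists were not called in Idh2 R172K. Of 37 interferon genes 4 rose and 4 fell (adjusted p 0.70, mean −0.14, median 0.027), with Gbp3 (log2 −0.97), Zbp1 (−1.44) and Ifi47 (−1.07) lower. Of 9 MHC class II genes 1 rose, H2-Oa (0.88), and 2 fell, H2-DMb1 (−0.78) and H2-DMa (−0.64, list adjusted p 0.51). Of 27 immediate early and heat shock genes 2 rose and 4 fell (adjusted p 0.42), with Hspa1a from 10.5 to 1.26 CPM (−3.12) and the chaperone Hsp90aa1 from 1110 to 640 CPM (−0.83). Hypoxia targets had 2 higher and 5 lower of 27 (adjusted p 0.76, mean −0.018, median 0.12), with Tpi1 (−0.62) and Egln3 (−0.75). Integrated stress genes had 2 higher and 6 lower of 25 (adjusted p 0.31), with the asparagine synthetase Asns (−1.27) and Shmt2 (−0.61). Cholesterol synthesis had 1 higher and 4 lower of 22 (adjusted p 0.31), with Ebp (−0.53). NF-kB targets had 3 higher and 3 lower of 21 (adjusted p 0.63, mean −0.089, median 0.27), with the chemokine Ccl3 from 15.5 to 0.575 CPM (−4.85), which lost its call without either sample of WT or Idh2 R172K (adjusted p up to 0.178). Ribosomal proteins had 5 higher and 1 lower of 83 (adjusted p 0.13, mean −0.033, median 0.070), and the 6 sex-linked genes had 0 called (adjusted p 0.57). Without WT sample 2 MHC class II lay lower (0.046) and ribosomal proteins higher (0.0056), and without Idh2 R172K sample 1 cholesterol synthesis (0.025) and interferon genes (0.0495) lay lower. In no fit was the adjusted p with an estimated correlation below 0.447. Adjusted over the list alone the counts were the same for interferon, MHC class II, heat shock, hypoxia, cholesterol and NF-kB genes, 2 and 7 for integrated stress, and 0 and 1 for ribosomal proteins.

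The count of 3365 genes stands beside 4998 at an unadjusted p under 0.05 and 2411 by DESeq2, 927 higher and 1484 lower. It was 1808 without WT sample 1, with 671 higher and 1137 lower, 1792 without WT sample 2, 2235 without Idh2 R172K sample 1 and 1706 without Idh2 R172K sample 2. In female cells alone 1085 passed. With equal class weights 2818 genes passed, and Idh1 (log2 0.37), Irf8 (0.28) and Rhag (0.87) turned their direction. These weights left out the erythroid-like cells and the other classes with too few cells in some pool. Of the 82 named entries, 20 lost their call with some pool left out.

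Cell classes were read from 21 clusters, of which 12 were named and 5 held over 90% Idh2 R172K cells. Those 5 held 85.1 and 87.4% of the Idh2 R172K cells, so most cells of this group clustered apart. Erythroid-like cells made up 1.70 ± 1.4% of WT cells, 0.827% in Idh1 R132H, 0.874% in Idh2 R140Q and 0.037% in Idh2 R172K. The log2 ratio of Idh2 R172K to WT was −5.16 ± 0.99 (adjusted p 2.6e-05), −5.11 (0.00017) when clusters were made without called genes, and −3.94 without WT sample 1. Granulocyte-monocyte-primed-like cells made up 13.3 ± 0.57% in WT, 21.2 ± 7.0% in Idh1 R132H, 9.47 ± 6.2% in Idh2 R140Q and 2.65 ± 0.38% in Idh2 R172K (−2.33, adjusted p 0.0020). This call was lost when expression was centred within samples (−0.82, adjusted p 0.22). Without called genes the share went from 9.20% in WT to 3.17% in Idh2 R172K. The exact permutation test over the 4 groups, whose smallest p is 0.00952, could not call a class that differs alone, and its lowest adjusted p was 0.229 in the main clusters and 0.0857 (macrophage-monocyte-like) without called genes.

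Megakaryocyte-like cells made up 5.70 ± 1.8% in WT, 6.46% in Idh1 R132H, 5.81% in Idh2 R140Q and 0.199 ± 0.12% in Idh2 R172K (log2 −4.85, adjusted p 3.8e-06). HSC-like cells made up 9.91, 8.14, 13.2 and 0.437% in the same order (−4.45). The size of both falls rests on naming conditions set after seeing the data. Those conditions kept 3 clusters led by Selp, Itga2b, Lag3, Smagp and Perp out of the megakaryocyte-like class, which held 0.0937% of WT, 0.163% of Idh1 R132H, 0.251% of Idh2 R140Q and 60.6% of Idh2 R172K cells. A cluster kept out of the HSC-like class held 0.344, 0.212, 0.868 and 12.5%. With the looser rule the megakaryocyte-like log2 ratio reversed to 3.39 and the HSC-like ratio to 0.34 (adjusted p 0.54). In the centred clustering the HSC-like ratio was −0.86 (adjusted p 0.063), and −0.84 (0.016) with the looser rule, from 9.25 to 5.16% of cells. Without called genes it was −0.92 under either rule (0.14 and 0.11). Lymphoid-primed-like cells made up 26.5% in WT and 18.1 ± 5.6% in Idh2 R172K (−0.55, adjusted p 0.37). B-lineage-like cells made up 0.129% in WT, 0.253% in Idh1 R132H, 0.929% in Idh2 R140Q (log2 2.94, adjusted p 0.029) and 0.698% in Idh2 R172K (2.41, adjusted p 0.024), from 0 to 33 cells per pool. The Idh2 R140Q ratio was 1.37 (adjusted p 0.93) without its sample 2, and without WT sample 1 the adjusted p was 0.22 for Idh2 R140Q and 0.17 for Idh2 R172K. No class passed in Idh1 R132H against WT by edgeR, and dendritic-like and T-NK-innate-lymphoid-like shares passed against WT in no mutant.

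**Figure D3:**
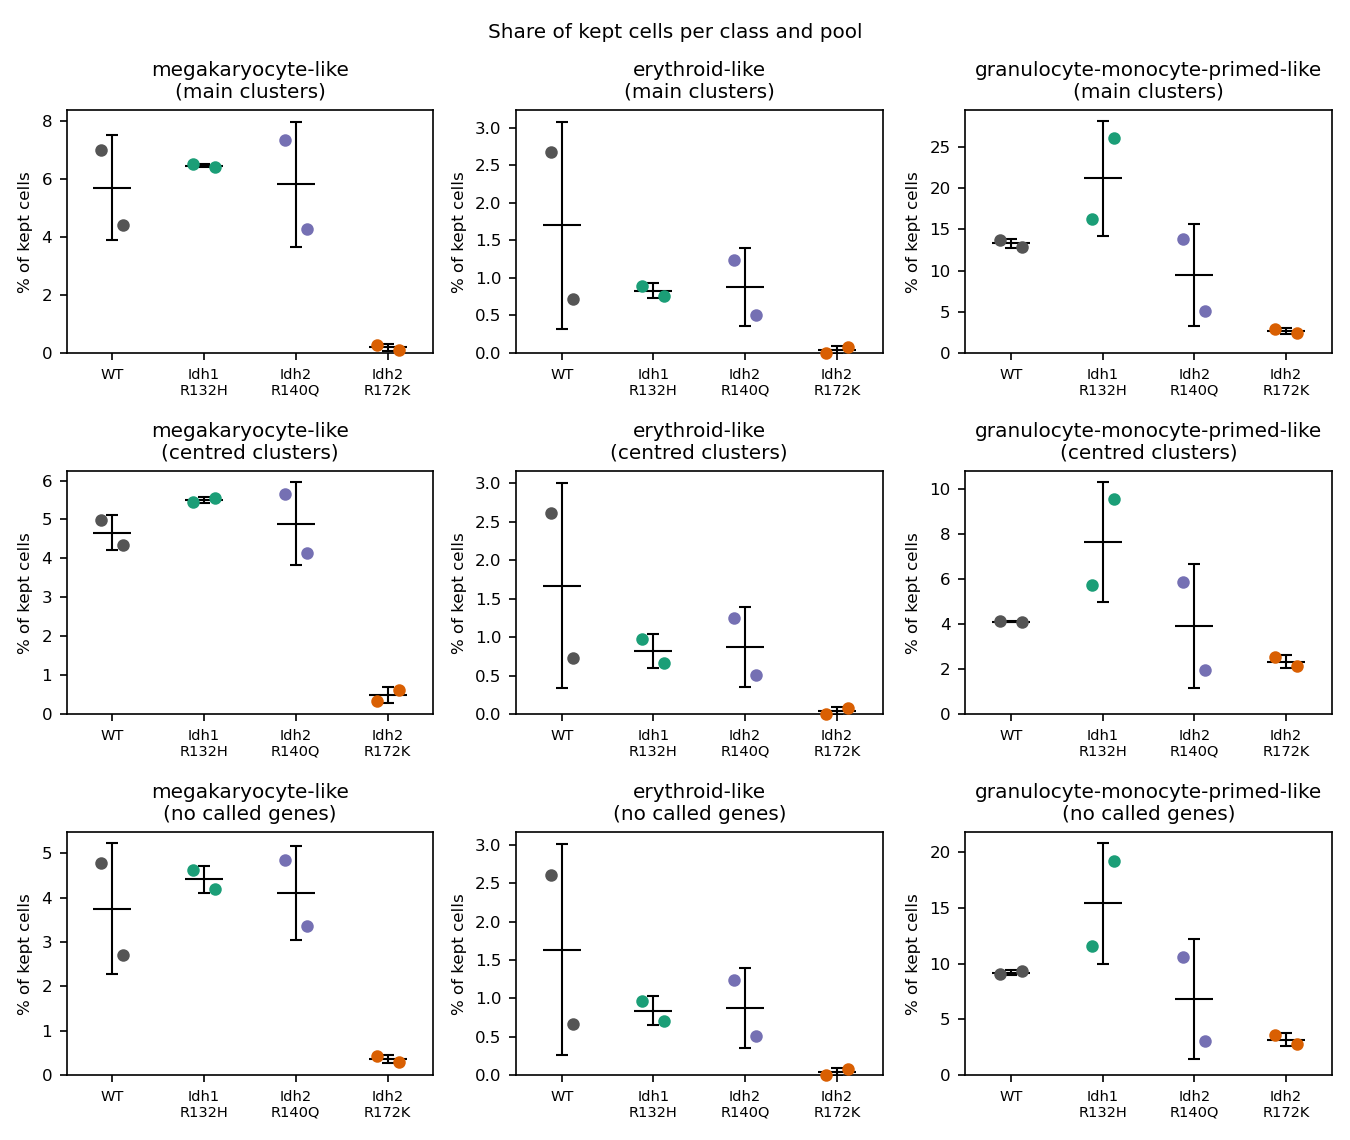
Share of kept cells (vertical axes, %) in 3 classes per pool, for the main clusters, for clusters centred within samples and for clusters made without called genes, with points for pools, bars for means and whiskers for the SD of 2 pools. The Idh2 R172K pools lie at 0 and 0.0734% for erythroid-like cells in the main clusters, and the megakaryocyte-like panels use the stricter naming conditions.

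Cells rich in Pf4, a platelet chemokine, were counted without clusters, with a threshold of 5 UMIs chosen after seeing the data. There were 22 and 10 such cells in the WT pools, 19 and 28 in Idh1 R132H, 11 and 19 in Idh2 R140Q, and 1 and 1 in Idh2 R172K. The shares were 1.34 and 0.659% in WT and 0.0479 and 0.0367% in Idh2 R172K, with exact binomial 95% bounds up to 0.266 and 0.204% in the latter. Shares of cells with each of 9 markers were read in cells thinned to 3000 UMIs, by an exact permutation test over all 4 groups. It could not call a marker that differs alone, since its smallest p of 0.00952 adjusts to 0.0857. Gata1, the erythroid and megakaryocyte regulator, was seen in 2.13% of WT and 0.222% of Idh2 R172K cells (adjusted p 0.446), beside 0.200% in lymphoid-primed-like cells, which should lack it. Background shares in such classes were 16.4% for Cd48 (HSC-like), 6.75% for Dntt and 3.37% for Flt3 (megakaryocyte-like), 6.02% for Mpo (B-lineage-like), 2.13% for Mki67 (HSC-like) and under 1% for the others. Dntt, the terminal transferase of lymphoid progenitors, was seen in 34.4 ± 1.6% and 17.2 ± 5.3% (adjusted p 0.30), and Cd48 in 36.9 and 31.6% (adjusted p 0.0857). Without thinning Gata1 was seen in 6.87 and 0.952%, and Dntt in 53.7 and 25.1%. Procr (6.45 and 6.63%), Slamf1 (1.03 and 0.885%), Flt3 (22.5 and 19.9%), Mpo (35.5 and 43.8%), Pf4 (3.62 and 2.58%) and Mki67 (20.5 and 18.7%) were the others.

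Within lymphoid-primed-like cells 1870 of 10664 genes passed in Idh2 R172K against WT, 810 higher and 1060 lower, beside 844 by DESeq2 (290 higher and 554 lower) and 1161 with the same number of cells per sample. The phosphodiesterase gene Pde4d rose from 21.5 to 133 CPM (log2 2.63), the receptor gene Klrd1 rose (2.99), and Igfbp7 rose (3.61). Ccnd1 (−5.13) and Padi4 (−4.40) fell, and Slc16a11 went from 34.3 CPM to no counts. Within granulocyte-monocyte-primed-like cells 1393 genes passed, beside 690 by DESeq2, 863 with the same number of cells and 744 in the centred clustering, with the galectin gene Lgals3 (4.97), Mycl (5.19) and Upb1 (5.32) higher and Gstt2 (−5.33), Fcho1 (−3.45) and Sdsl (−3.23) lower. Lgals3 lost its call without either sample of WT, Idh1 R132H or Idh2 R172K (adjusted p up to 0.178) and with the replicate number as a block (0.070), and both Lgals3 (0.126) and Sdsl (0.219) in the centred clustering. In HSC-like cells of the centred clustering 206 genes passed, beside 53 by DESeq2, with Lag3 (2.47), Selp (2.54) and Tmem215 (3.86) higher, Padi4 (−3.96) and Ctsg (−3.65) lower, and Wfdc2 from 24.0 CPM to no counts. Of the lymphoid-primed-like cells of Idh2 R172K 72.3% lay in cluster 13, while those of the other groups lay most often in clusters 3 or 6. Clusters 7 and 15 held the granulocyte-monocyte-primed-like cells of every group, in different proportions. Cluster 15 held 77% of them in Idh2 R172K and 26.3, 34.8 and 35.2% in WT, Idh1 R132H and Idh2 R140Q. Tests within either class, lymphoid-primed-like or granulocyte-monocyte-primed-like, do not separate a shift between its clusters from a change of expression. In lymphoid-primed-like cells 1188 passed without WT sample 1, 1035 without WT sample 2 and 1096 without Idh2 R172K sample 1. In granulocyte-monocyte-primed-like cells 723 passed without WT sample 2 and 538 without Idh2 R172K sample 2, and in HSC-like cells 126, 116 and 94 without WT sample 1, WT sample 2 and Idh2 R172K sample 2. Idh1 R132H had 0 genes in lymphoid-primed-like cells by edgeR (401 at an unadjusted p under 0.05, 0 by DESeq2), and Idh2 R140Q had 1, Hddc3 (1.82). In HSC-like cells Idh1 R132H had 1 gene, Ifi27 (0.75, adjusted p 0.0497). This call was lost by DESeq2 (adjusted p 1, 0 genes called) and without WT sample 1 (0.856), Idh1 R132H sample 1 (0.178) or sample 2 (0.0895), and 15 genes passed without WT sample 2.

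Between the mutants, Idh2 R172K differed from Idh2 R140Q at 2168 genes, 928 higher and 1240 lower. Perp (log2 3.57 ± 0.22), Smagp (3.07), Selp (2.26) and Pcdh7 (2.15) were highest, and Ccl3 (−5.33), Padi4 (−3.80), Bex4 (−3.29) and the antisense gene Tnfsf13os (−2.93) lowest. The list calls that follow had an adjusted p of 0.76 to 0.90 with an estimated correlation. Erythroid genes fell in 4 of 24 cases and 13 adjusted over the list alone (adjusted p 4.9e-07), S phase genes in 15 (7.2e-05), oxidative phosphorylation in 11 (7.6e-05) and cholesterol synthesis in 7 (0.0014), with 0 members higher in these 4 lists (0.76 to 0.85 with an estimated correlation). Heme synthesis (0.018), MHC class II (0.042), glycolysis (0.015) and the TCA cycle (0.036) fell too, and dioxygenases (0.015) and p53 targets (0.036) rose, all at an adjusted p of 0.76 to 0.90 with an estimated correlation, although 2 dioxygenase genes fell and 1 p53 target moved each way. Within granulocyte-monocyte-primed-like cells the MHC class II mean turned to 0.28. The call of heme synthesis and of glycolysis was lost without Idh2 R140Q sample 1 (0.052), and that of the dioxygenases without Idh2 R140Q sample 2 (0.058). The TCA cycle lost it without WT sample 2 (0.053), Idh2 R140Q sample 1 (0.15), Idh2 R172K sample 1 (0.11) or sample 2 (0.070), and the p53 targets without WT sample 2 (0.053), Idh2 R140Q sample 1 (0.12) or Idh2 R172K sample 1 (0.16). MHC class II lost it without Idh1 R132H sample 1 (0.056) or sample 2 (0.054), Idh2 R140Q sample 1 (0.052) or sample 2 (0.17), or Idh2 R172K sample 2 (0.094). The gene count was 1101 without Idh2 R140Q sample 1, 1228 without Idh2 R172K sample 1 and 970 without Idh2 R172K sample 2, and 1263 in female and 1315 in male cells alone. Selp had an adjusted p of 0.0542 and 0.0718 without Idh2 R172K sample 1 and sample 2, and Ccl3 lost its call in 5 such fits.

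Against Idh1 R132H, Idh2 R172K differed at 4338 genes, 1998 higher and 2340 lower. Perp (log2 3.28), Smagp (3.17), Pcdh7 (2.62) and Selp (2.44) were highest, Padi4 (−3.81), Ctsg (−3.04) and Casp1 (−2.78) were among the lowest, and Car1 was at least 732-fold lower (413-fold and 319-fold without Idh2 R172K sample 1 and sample 2). Of 25 HSC genes 11 rose and 2 fell (adjusted p 0.017), of the transcription factors 13 rose and 4 fell (0.035), and of the dioxygenases 15 rose and 3 fell (0.0034), each at an adjusted p of 0.551 with an estimated correlation. The HSC list mean turned to −0.12 in lymphoid-primed-like cells, −0.48 in granulocyte-monocyte-primed-like cells and −0.086 in HSC-like cells of the centred clustering. S phase genes fell in 30 cases and rose in 0 (2.4e-07), oxidative phosphorylation in 32 and 1 (2.4e-07), the TCA cycle in 16 and 1 (0.00014), erythroid genes in 11 and 2 (0.00014) and G2 and M phase genes in 20 and 0 (0.00082), at 0.551 to 0.562 with an estimated correlation. Within granulocyte-monocyte-primed-like cells the means turned to 0.72 for granule and myeloid genes, 0.23 for G2 and M phase genes and −0.042 for transcription factors, the first 2 called as higher (adjusted p 0.00012 and 0.0059, and 0.70 and 0.716 with an estimated correlation). By fry 9 lists were called, among them imprinted genes (0.036) and p53 targets (0.048), which camera did not call. Granule and myeloid (0.0071), heme (0.0048), glycolysis (0.0021), 2-hydroxyglutarate (0.019) and cholesterol (0.012) lists fell as well, and with an estimated correlation the adjusted p of the 13 lists was 0.551 to 0.562. HSC genes lost the call without Idh1 R132H sample 2 (0.084) or Idh2 R172K sample 2 (0.081), granule and myeloid genes without Idh1 R132H sample 2 (0.091), and cholesterol synthesis without Idh1 R132H sample 1 (0.051) or Idh2 R172K sample 2 (0.18). Transcription factors lost it without WT sample 1 or sample 2 (0.052 each), Idh1 R132H sample 2 (0.11) or Idh2 R172K sample 1 (0.062). The gene count was 1863 without Idh1 R132H sample 2 and 2367 without Idh2 R172K sample 2, and 1737 in female cells alone. Selp had an adjusted p of 0.0557 without Idh1 R132H sample 2, Ctsg lost its call without Idh1 R132H sample 2 or either Idh2 R172K sample (up to 0.123), and Car1 in 6 fits (up to 0.165).

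Between Idh2 R140Q and Idh1 R132H 1 gene passed, Hddc3 (log2 1.78 ± 0.17, adjusted p 0.0017), beside 1344 at an unadjusted p under 0.05. DESeq2 called 15 other genes and gave Hddc3 no adjusted p (log2 1.77, unadjusted p 1.3e-14), since it gave one to only 2786 genes here. In female cells Hddc3 did not pass (1.35, adjusted p 0.995) and 0 genes did, and in male cells it passed (2.30, 1.4e-05) among 40. With edgeR in all cells its adjusted p was 0.105 and 0.274 without Idh1 R132H sample 1 and sample 2, which left 0 genes, and 14 and 12 genes passed without Idh2 R140Q sample 1 and sample 2. G2 and M phase genes lay lower (adjusted p 3.6e-15), with 17 lower adjusted over the list alone, and HSC genes lay higher (1.6e-06), with 4 higher, both at an adjusted p of 0.536 with an estimated correlation. Ribosomal proteins (8.1e-05) and transcription factors (0.011) lay higher (0.584 and 0.536 with an estimated correlation). S phase (3.6e-05), granule and myeloid (6.5e-05), TCA (3.3e-06), oxidative phosphorylation (1.5e-05), interferon (0.0041), heme (0.015), glycolysis (0.0094), 2-hydroxyglutarate (0.0094) and stress response (0.011) lists lay lower, at an adjusted p of 0.536 to 0.60 with an estimated correlation. Within granulocyte-monocyte-primed-like cells the means turned to 0.24 for granule and myeloid genes (adjusted p 0.0032, 0.81 with an estimated correlation) and 0.016 for S phase genes. In HSC-like cells of the centred clustering they turned to 0.042 for heme synthesis and 0.0049 for oxidative phosphorylation. In female cells they were 0.022 for oxidative phosphorylation and 0.053 for stress response. Without Idh1 R132H sample 2 the call was lost for granule and myeloid genes (0.090), glycolysis (0.090), heme synthesis (0.095), S phase genes (0.20), 2-hydroxyglutarate metabolism (0.27), stress response (0.39) and transcription factors (0.32), and without Idh1 R132H sample 1 for interferon genes (0.10). Without Idh2 R140Q sample 2 it was lost for granule and myeloid genes and heme synthesis (0.19 each), interferon genes (0.29), glycolysis (0.15), oxidative phosphorylation (0.34), 2-hydroxyglutarate metabolism (0.13), stress response (0.13) and transcription factors (0.14).

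Fold changes against WT were compared between mutants across 12777 genes, which are not independent replicates. Idh2 R140Q and Idh2 R172K had r = 0.45 and a covariance of 0.0930, beside 0.0400 for simulated unchanged groups with the same WT pools. Without Idh2 R140Q sample 2 this r was 0.29 (covariance 0.0808), and without WT sample 2 the covariance was 0.157. Idh1 R132H and Idh2 R172K had r = 0.21 beside 0.52 and a covariance of 0.0401 beside 0.0398, and Idh1 R132H and Idh2 R140Q had r = 0.47 beside 0.50 and 0.0415 beside 0.0399. Without WT sample 1 and sample 2 the covariance was 0.0754 and 0.0976 in the former pair (r 0.29 and 0.37) and 0.0851 and 0.0921 in the latter. At genes with at least 10 CPM r was 0.050 in the former and 0.26 in the latter, and with equal class weights 0.32 in the former. With a different WT pool for each mutant, r was 0.25 and 0.19 for the Idh2 mutants (covariance 0.0642 and 0.0482), 0.068 and −0.038 for Idh1 R132H with Idh2 R172K, and 0.078 and −0.00051 for Idh1 R132H with Idh2 R140Q. Of the called genes of Idh2 R140Q, Lag3 was also higher and Xlr4b also lower in Idh2 R172K, so 1 gene was shared in each direction, beside 0.239 higher and 0.144 lower for independent lists, in comparisons that share their WT pools. In Idh2 R140Q both calls were lost without WT sample 1, WT sample 2 or Idh2 R140Q sample 2. The call of Xlr4b was also lost without Idh1 R132H sample 2 (adjusted p 0.0599) or Idh2 R140Q sample 1. Genes called in Idh2 R172K without WT sample 1 (1808) or sample 2 (1792) were read in the other mutants against that WT sample alone, so that the choice of genes did not use it, a comparison added after the data were seen. Idh2 R140Q had the same sign in 67.8 and 72.5% of them, and Idh1 R132H in 42.0 and 41.7%. In female cells the shares were 44.2 and 49.1% for Idh2 R140Q and 37.7 and 41.2% for Idh1 R132H, and in male cells 71.1 and 73.7% and 42.5 and 45.4%.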

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

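Most tests below were chosen after the results were seen. They are the tests of the sex split, depth, class mix, a mouse without the mutation, clustering, cluster naming and the sort gate. The prediction for the genes around Idh2 was written before its test was run, but for a pattern of Hddc3 already seen in these data.

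The effect of Idh2 R140Q against WT differed between female and male cells at 185 genes, 142 of them with the higher fold in female cells, and that of Idh2 R172K at 237 genes, 175 of them higher in female cells, of 11987 tested by an edgeR interaction term. For Idh1 R132H the count was 0, beside 377 genes at an unadjusted p under 0.05. Among named genes, the fold of Idh2 R140Q in female minus that in male cells was 2.94 on the log2 scale for Hspa1a, 0.47 for the chaperonin gene Hspe1 and 0.46 for the tubulin gene Tubb4b. It was −0.88 for Plek, −1.41 for Slc16a11 and −0.37 for mt-Co1. For Idh2 R172K the difference was 0.39 for Hspe1, 0.51 for Tpi1 and 0.50 for Shmt2. Where a pool holds 2 mice, the sex of its cells cannot be separated from the individual mouse, and no biological explanation was tested. In Idh2 R140Q sample 1 the female cells had a low Hddc3 level (9.65 CPM, beside 32.5 in its male cells). Whether a mouse there lacked the mutation stays open, as described below. Calling a cell female or male needs UMIs of few genes, so the split also selects cells by depth, which was not matched. In the WT pools 428 and 614 female cells held 4397425 and 7943009 UMIs, and 723 and 592 male cells 9649364 and 9709427. In the Idh2 R140Q pools 487 and 691 female cells held 8395876 and 8169798, and 250 and 1025 male cells 3813826 and 12718534.

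A first pattern is the change of 3365 genes in Idh2 R172K. In cells with at least 6000 UMIs 90.9% of the called genes were called again with the same sign. This argues against the shallowest cells as the source of the calls. Most cells pass this minimum and it does not match depth between groups, so fewer UMIs per cell as such stays open. With equal class weights 69.7% of the called genes were called again with the same sign. This argues against another mix of HSC-like, granulocyte-monocyte-primed-like and lymphoid-primed-like cells as the whole cause. Those weights left out the other named classes, which had too few cells in some pool. The unnamed clusters count there as 1 class with 51.8% of the weight. A mix among them, or among the clusters within a named class, was not tested. As the whole cause, another mix of the sexes is argued against by a correlation of 0.890 across called genes between female and male folds. The genes were called in sums that include these cells, which favours such agreement. In female cells alone, 985 of the 3365 called genes were called again with the same sign, and in male cells alone 2503. Each part holds fewer cells than the whole. Of the called genes with a value, 31 of 3188 turned sign in female cells and 2 of 3201 in male cells. The median absolute log2 fold was 0.45 in female and 0.64 in male cells, beside 0.56 in all kept cells. The labels give no batch, so a batch shared by both pools was not tested.

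A second pattern is the level of Hddc3 in Idh2 R140Q, which was high except in the female cells of sample 1 (9.65 CPM, beside 32.5 in its male cells and 29.7 and 28.1 in the female and male cells of sample 2). Hddc3 lies close to Idh2, so DNA of another strain around the targeted allele is a candidate explanation. Of 65 tested genes within 5 Mb of Idh2, 9.23% were at an unadjusted p under 0.05, beside 4.62% elsewhere (Fisher's exact test, 2-sided p 0.126), which leaves this open. In Idh2 R172K, a mutation of the same gene, Hddc3 stood at 8.27 to 10.3 CPM over female and male cells, beside 6.08 to 8.18 in WT. There 40.0% of the genes near Idh2 were at such a p, beside 39.2% elsewhere. Whether both alleles have the same flanking sequence is not known here. A mouse without the mutation in sample 1 stays open. The 95% Poisson interval of Xlr4b in those female cells ended at 5.24 CPM. This was below WT but above the 5.16 and 5.02 CPM in female cells of Idh1 R132H. Xlr4b was picked because it was lower in these same pools, so a low value there cannot decide.

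The last pattern is the lower share of erythroid-like and megakaryocyte-like cells in Idh2 R172K. For erythroid-like cells, clusters set by the changed genes are argued against by the log2 ratio of −5.11 without called genes. For megakaryocyte-like cells the conditions of the naming rule stay open as the cause of the fall. The ratio was 3.39 with the looser rule. Pf4-rich cells, counted without clusters, numbered 22 and 10 in WT and 1 and 1 in Idh2 R172K. Under the stricter conditions the share went from 4.66% in WT to 0.480% in Idh2 R172K in the centred clustering. Without called genes it went from 3.75 to 0.362%. In the centred clustering the looser rule added a cluster through Itga2b, Plek and Selp, which all rose in Idh2 R172K. Another position of the sort gate may also have contributed to the erythroid-like share and stays open, with a log2 fold change of 0.43 for Kit (adjusted p 0.0494) and −0.33 for Ly6a, which encodes Sca1 (adjusted p 0.304).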

How the results depend on the processing

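The splits by sex, the removal of cells with both sexes' transcripts, the depth minimum of 6000 UMIs, the HSC-like class of the centred clustering, the tests within classes of the centred clustering, the shared folds within classes or with equal weights, and the looser naming rule were chosen after the results were seen, and the other alternatives before. For single genes 2204 results kept their direction and side of the threshold, 164 lost the call and 3 reversed. For lists 1981 stayed, 358 lost and 112 gained the call, and 45 reversed. For classes 766 stayed, 59 lost and 2 gained the call, and 13 reversed. A change of sign between values that were both not called counts as staying. Except where a count is shown to follow from fewer cells or fewer samples, the cause was not tested. List means include fitted folds of genes at 0, which weighs on the erythroid list. Depth limits the calls of genes near 1 CPM, and with 2 pools per group no pool can be tested as an outlier.

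Genes changed without the low-count filter numbered 195 for Idh1 R132H against WT, 258 for Idh2 R140Q against WT and 334 for Idh2 R140Q against Idh1 R132H. Fits of only the 2 groups compared gave 10, 6 and 10. In female cells only, 1 gene passed for Idh2 R140Q against WT, 1085 for Idh2 R172K against WT, 1263 against Idh2 R140Q and 1737 against Idh1 R132H, and 0 for Idh2 R140Q against Idh1 R132H. In male cells only, 1315 passed for Idh2 R172K against Idh2 R140Q and 40 for Idh2 R140Q against Idh1 R132H. DESeq2 gave 15 in the last comparison. With equal class weights, which left out erythroid-like cells, the folds of Idh1 (0.37), Irf8 (0.28) and Rhag (0.87) in Idh2 R172K against WT reversed.

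Within classes, the count without the low-count filter was 13 and 46 in lymphoid-primed-like cells (Idh1 R132H, then Idh2 R140Q, against WT), 15 and 19 in granulocyte-monocyte-primed-like cells and 3 and 5 in HSC-like cells of the centred clustering. DESeq2 gave 2 for Idh2 R140Q and 844 for Idh2 R172K in lymphoid-primed-like cells, 1 for Idh1 R132H and 690 for Idh2 R172K in granulocyte-monocyte-primed-like cells, and 0 and 53 in HSC-like cells. With classes of the centred clustering the counts were 1 and 2 in lymphoid-primed-like cells and 1 (Idh2 R140Q) and 744 (Idh2 R172K) in granulocyte-monocyte-primed-like cells. With the same number of cells they were 1, 2 and 1161 in lymphoid-primed-like cells and 863 for Idh2 R172K in granulocyte-monocyte-primed-like cells.

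The samples share only a replicate number: deviations of same-numbered samples correlated at 0.19, 0.21, 0.068, −0.082, 0.015 and 0.0070. With the replicate block the gene counts were 0, 2, 3374, 2138, 4346 and 1, in the order Idh1 R132H, Idh2 R140Q and Idh2 R172K against WT, Idh2 R172K against Idh2 R140Q and against Idh1 R132H, and Idh2 R140Q against Idh1 R132H. Lag3 in Idh2 R140Q against WT had an adjusted p of 0.061. Within classes the replicate block gave 3 and 5 in lymphoid-primed-like, 13 and 6 in granulocyte-monocyte-primed-like and 5 and 2 in HSC-like cells for Idh1 R132H and Idh2 R140Q.

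With an estimated correlation 0 lists were called in each of the 6 comparisons. By fry 0 were called for Idh1 R132H and Idh2 R140Q against WT, 3 for Idh2 R172K against WT, 0 for Idh2 R172K and Idh1 R132H against Idh2 R140Q, and 9 for Idh2 R172K against Idh1 R132H. Female cells only gave 3 lists for Idh2 R172K against WT, 5 against Idh2 R140Q and 8 for Idh2 R140Q against Idh1 R132H. Male cells only gave 5 for Idh1 R132H and 17 for Idh2 R140Q against WT. Within lymphoid-primed-like cells there were 3 (Idh1 R132H against WT), 5 (Idh2 R172K against Idh2 R140Q) and 8 (Idh2 R140Q against Idh1 R132H). Within granulocyte-monocyte-primed-like cells the 6 comparisons gave 0, 3, 6, 5, 5 and 5, and within HSC-like cells of the centred clustering 5, 1, 3, 4, 4 and 6, in the order above.

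Mean log2 folds of lists that reversed were as follows. In female cells only they were 1.48 for erythroid genes in Idh1 R132H against WT. For Idh2 R140Q against WT they were 0.12 for lymphoid priming (where the test's direction turned), 0.093 for S phase, 0.17 for interferon, 0.051 for the TCA cycle and 0.074 for oxidative phosphorylation. For Idh2 R140Q against Idh1 R132H they were 0.059 for lymphoid priming, −0.61 for erythroid, 0.022 for oxidative phosphorylation and 0.053 for stress response genes. Within lymphoid-primed-like cells they were 0.0037 for G2 and M phase, −0.011 for the TCA cycle and −0.0080 for 2-hydroxyglutarate metabolism in Idh1 R132H against WT, and for HSC genes −0.10 in Idh2 R140Q against WT and −0.12 in Idh2 R172K against Idh1 R132H. Within granulocyte-monocyte-primed-like cells they were −0.012 for S phase in Idh1 R132H against WT and 0.028 for granule and myeloid genes in Idh2 R140Q against WT. In the same cells Idh2 R172K against WT had −0.65 for HSC, 0.51 for granule and myeloid and 0.25 for G2 and M phase genes, and against Idh2 R140Q −0.67 for HSC, 0.48 for granule and myeloid and 0.28 for MHC class II genes. Against Idh1 R132H it had −0.48 for HSC, 0.72 for granule and myeloid, 0.23 for G2 and M phase and −0.042 for transcription factor genes, and Idh2 R140Q had 0.24 for granule and myeloid and 0.016 for S phase genes. Within HSC-like cells of the centred clustering the values were −0.14 for MHC class II in Idh1 R132H against WT. For Idh2 R140Q against WT they were −0.068 for HSC, −0.050 for megakaryocyte, 0.066 for MHC class II (direction of the test), 0.082 for TCA cycle and 0.014 for oxidative phosphorylation genes. They were 0.049 for the TCA cycle in Idh2 R172K against WT, −0.086 for HSC genes in Idh2 R172K against Idh1 R132H, and 0.042 for heme and 0.0049 for oxidative phosphorylation in Idh2 R140Q against Idh1 R132H.

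Classes called in Idh2 R140Q against WT went from 1 to 0 at Leiden resolutions 0.5 and 1.5, in the centred clustering, without called genes, with the stricter cell filter, without Scrublet calls, in both of those clusterings with the looser naming rule, and by limma on log odds. In Idh2 R172K against WT they went from 5 to 2 in the centred clustering and to 3 without called genes and with the looser rule. In Idh2 R172K against Idh2 R140Q they went from 6 to 3 without called genes, with either naming rule. At resolution 0.5 the dendritic-like log2 ratio reversed to 0.46 against Idh2 R140Q and 0.16 against Idh1 R132H. From WT to Idh2 R172K the share went from 0.496 to 1.31% at that resolution and from 0.400 to 0.211% in the main clusters. The megakaryocyte-like ratio of Idh2 R172K against WT, Idh2 R140Q and Idh1 R132H reversed to 3.39, 3.34 and 3.20 with the looser rule, to 0.95, 0.59 and 0.86 with the looser rule in the centred clustering, and to 1.94, 1.67 and 1.94 with the looser rule without called genes. The HSC-like ratio reversed to 0.34 against WT and 0.64 against Idh1 R132H with the looser rule.

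Correlations of folds for Idh1 R132H with Idh2 R172K were 0.32 with equal class weights, 0.30 within lymphoid-primed-like and 0.26 within granulocyte-monocyte-primed-like cells, and 0.050 at genes with at least 10 CPM, where Idh1 R132H with Idh2 R140Q had 0.26. With separate WT samples they were 0.078 and −0.00051 for Idh1 R132H with Idh2 R140Q, 0.068 and −0.038 for Idh1 R132H with Idh2 R172K, and 0.25 and 0.19 for the Idh2 mutants.

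With 1 pool left out in turn, gene counts ranged from 0 to 1, 0 to 13, 1706 to 3678, 970 to 2238, 1863 to 4583 and 0 to 14 in the 6 comparisons in the order above. Lists called ranged from 3 to 12, 2 to 12, 7 to 12, 5 to 10, 11 to 14 and 5 to 16. Classes called ranged from 0 to 0, 0 to 1, 4 to 5, 3 to 6 and 4 to 6 in the first 5. Counts within classes against WT, for Idh1 R132H, Idh2 R140Q and Idh2 R172K, ranged from 0 to 6, 1 to 11 and 1035 to 1923 in lymphoid-primed-like, 0 to 3, 0 to 8 and 538 to 1453 in granulocyte-monocyte-primed-like and 0 to 15, 1 to 9 and 94 to 232 in HSC-like cells. Marker genes called ranged from 0 to 0, in a test that could not call a marker that differs alone. Correlations of folds ranged from 0.34 to 0.65 (Idh1 R132H with Idh2 R140Q), 0.16 to 0.37 (Idh1 R132H with Idh2 R172K) and 0.29 to 0.54 (the Idh2 mutants). List means that reversed or whose test turned were 0.96 for erythroid genes without WT sample 1 (lowest −0.96, without WT sample 2), and −0.016 for S phase genes and −0.0051 for the TCA cycle without Idh1 R132H sample 2, in Idh1 R132H against WT. They were −0.46 for erythroid genes without WT sample 2 and −0.00094 for oxidative phosphorylation without Idh2 R140Q sample 2, where the test's direction turned (lowest −0.16, without sample 1), in Idh2 R140Q against WT, and −0.14 for heat shock genes without Idh1 R132H sample 2 (highest 0.33, without sample 1) in Idh2 R140Q against Idh1 R132H.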

Other observations

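The score tests, the comparison without a shared sample, the both-sex count and the genes named below were chosen after the results were seen.

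More genes of the fixed lists changed in Idh2 R172K against WT than the rule for named genes takes. Among HSC genes, the angiopoietin receptor Tek rose (log2 1.71), as did Esam (0.90), Socs2 (0.83), Gata2 (0.45) and Meis1 (0.33), while Tcf15 (−0.65) and Gata3 (−0.59) fell. Among megakaryocyte genes, the integrin gene Itga2b (1.70), Gp5 (0.86) and Fli1 (0.38) rose. Gata1 fell (−2.83, adjusted p 0.040), and Klf1, the erythroid Kruppel-like factor, did not pass (−3.22, adjusted p 0.066). The p53 targets Mdm2 (0.31), Bbc3 (1.12) and Phlda3 (0.97) rose, and the imprinted RNA gene Meg3 rose (1.81). Xlr4b fell by 4.05 on the log2 scale (adjusted p 1.7e-07).

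Genes called in Idh2 R172K in a fit without WT sample 1 or without WT sample 2 gave a score, the mean log2 fold of the higher genes minus that of the lower, read against the WT sample left out. It was 0.257 ± 0.065 and 0.232 ± 0.12 in Idh2 R140Q, and −0.0071 ± 0.17 and −0.041 ± 0.11 in Idh1 R132H. In Idh2 R140Q it was 0.034 and 0.074 in female cells and 0.35 and 0.322 in male cells. The female values differed between pools, at −0.033 and −0.023 in Idh2 R140Q sample 1 and 0.10 and 0.17 in sample 2. The male values were 0.339 and 0.284 in sample 1 and 0.362 and 0.36 in sample 2. The female cells of sample 1 are those with the low Hddc3 level, so a difference between mice was not separated from sex. Without any shared sample, folds of Idh2 R140Q over Idh1 R132H and of Idh2 R172K over WT correlated at 0.26 across genes, with the same sign in 64.6%. The value was 0.21 in female and 0.29 in male cells, 0.17 with equal class weights, 0.21 within lymphoid-primed-like, 0.19 within granulocyte-monocyte-primed-like and 0.035 within HSC-like cells of the centred clustering.

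Folds in female and in male cells at 3157 genes called in Idh2 R172K correlated at 0.890 in Idh2 R172K, 0.158 in Idh2 R140Q and 0.156 in Idh1 R132H, with the same sign in 99.0, 43.7 and 66.3%. Xlr4b ranged from 8.19 to 11 CPM over the female and male cells of WT pools, from 5.02 to 6.86 in Idh1 R132H, from 2.88 to 3.93 in Idh2 R140Q and from 0.272 to 0.971 in Idh2 R172K.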
